A study of Mus musculus with 16 samples.

How the data were processed

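RNA of sorted CD4+CD90.1+ AND T cells was measured in 16 samples, 1 array each, on an Affymetrix mouse array with 45101 probe sets. Per the labels' protocols RNA was taken up in Trizol, amplified in 2 rounds and labelled with biotin. The deposited values are intensities that the authors made with RMA, per the submitters' processing notes, which give no version. The deposited maxima are far above what log2 values can reach, so the values were read as linear. They were used as log2(intensity + 1), with no further normalization, and this shrinks differences between dim genes. No array was identical to another, and the highest correlation within a group was 0.987.

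Groups were taken from the labels as antigen regime (none, transient, persistent) by treatment (PBS, or FGK45.5 against CD40). Of the probe sets 35890 were found in the table of gene names, 932 of them with several symbols, 9211 were not found and 64 were array controls. The 34945 probe sets with 1 symbol gave 18193 genes, each represented by its probe set with the highest mean. Of 129 named gene and comparison pairs with several probe sets, 28 had another of opposite sign, which passed in 0, blocked or not.

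Differences were tested with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8). A single linear model of 6 group means held all 16 arrays, with moderated t statistics, an intensity trend and no block. P-values were adjusted by Benjamini and Hochberg over all genes, and genes with an adjusted p under 0.05 were called. The comparisons were transient and persistent against no antigen and against each other, with PBS and with anti-CD40. To these came anti-CD40 against PBS in each regime, transient antigen with anti-CD40 against persistent antigen with PBS, and 2 interaction terms. A group left with 1 array in an alternative is assumed to vary like the other groups.

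Replicate numbers were checked for pairing before the fits were compared. Deviations from the group means correlated at 0.48 to 0.81 (median 0.68) in the 36 pairs of arrays with the same number. In the 70 pairs with different numbers the median was −0.53. All 16 arrays correlated best with an array of their own number. The numbers were therefore taken to pair the arrays, from the data and not from the labels. The same model with the replicate number as a fixed block was fitted beside it. Its values are given only where the block ends or adds a call or moves a count by over 1.5 times.

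The 27 gene lists with 550 genes, 497 of them measured, were: T cell identity, T cell activation, mitosis, DNA replication, naive and recirculating T cell, Th1 effector, Th2 and Th17, follicular helper, regulatory T cell, inhibitory receptors and anergy, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis, endoplasmic reticulum stress and folding, cell death and survival, trafficking and adhesion, B cell, plasma cell, dendritic cell and macrophage, NK cell and CD8 T cell, granulocyte, erythrocyte, stroma and endothelium, dissociation and immediate early and sex-linked. Each was tested with camera of limma at a preset correlation of 0.01 and adjusted over the lists of a comparison. Each test was repeated with an estimated correlation and with fry. Members were counted past the threshold over all genes and adjusted over the list alone. Medians of log2 differences are those of the fit named.

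Named genes followed a rule. It took the 6 largest increases and decreases past the threshold without overlap between arrays and with a higher group mean above the median probe set (4.37 in log2). Clone names, immunoglobulin and T cell receptor segments and sex-linked genes were left out. It added up to 4 of the largest members past the threshold from each list called or with 3 members past it. It also added 28 T cell genes chosen in advance, of which 27 are analysed here, and these are summarised where they did not pass. Where fewer than 6 genes passed, the 5 with the smallest p are named. Naming genes from the blocked fit by the same rule was decided after the values were seen. The groups, comparisons, tests, gene lists, rule and most alternatives were fixed before the data were examined.

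Alternatives were the replicate block, a block for 4 runs of consecutive array numbers, a fit of the compared groups alone and no intensity trend. Further ones were leaving out dim genes, the mean of a gene's probe sets, cyclic loess scaling, array weights, log2(intensity + 16) and leaving out each array. Replicates 1 and 3 only, and other alternatives for the blocked counts for the similarity of effects and for T cell identity, were added after the data had been seen. The model was tested on simulated data with the real replicate effects, normal noise of each gene's spread in the blocked fit and 200 of 18193 genes changed by 1, 2 or 3 on the log2 scale. For persistent against transient antigen with PBS it recovered 35, 90 and 98.5% of them, and 92.5, 100 and 100% with the block. For anti-CD40 under transient antigen the shares were 23, 81.5 and 96.5% (blocked 87.5, 100 and 100%). Under persistent antigen they were 34.5, 85 and 96% (blocked 97.5, 100 and 100%). At a change of 1 for persistent against transient antigen the block called 21 unchanged genes beside them. A list shifted by 1 in that comparison was called by camera, and no other. With noise drawn gene by gene this cannot test false calls from correlated members. Genes without overlap between the arrays of the groups were 10.1% (transient against no antigen), 18% (persistent against no antigen), 17.5% (persistent against transient antigen) and 3.48% (anti-CD40 under persistent antigen), against 10% by chance for 3 against 3. With a group of 2 they were 21.6% (anti-CD40 under transient antigen), 10.8% (anti-CD40 without antigen), 12.2% and 27.7% (persistent against transient and no antigen with anti-CD40) and 14.5% (transient with anti-CD40 against persistent with PBS), against 20% by chance. For 2 against 2 they were 28.2% against 33.3%. Transcripts without a gene symbol were left out.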

Results

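The 16 arrays measured RNA of AND T cells, CD4+ cells whose transgenic T cell receptor recognises a peptide of moth cytochrome c. Lymph node cells carrying the CD90.1 marker were transferred into B10.BR mice. The CD4+CD90.1+ cells were flow sorted after 60 h. The recipients' dendritic cells made the peptide under doxycycline control, either transiently or throughout, and recipients lacking the Ii-rTA transgene made none. Each of these 3 antigen regimes was combined with PBS or with FGK45.5, a stimulatory antibody against CD40 that activates dendritic cells. The 6 groups held 3 arrays each, except no and transient antigen with anti-CD40, which held 2 each (replicates 1 and 2). The no-antigen recipients therefore differed in genotype as well as in antigen. In replicate 2 the arrays without antigen also came from another run of consecutive array numbers than those with antigen. By title (no, short and long dox) the regimes also differed in doxycycline exposure, whose own effect was not tested. Nothing in the labels says whether replicates came from separate animals, so p-values measure the spread between these samples, part of which may be technical. Per array the median intensity lay between 18.2 and 21.3. Differences below are on the log2(intensity + 1) scale, given as the estimate ± its standard error from limma with p-values adjusted over 18193 genes. Arrays left out are named by antigen, treatment and replicate, in brackets after the count without them. Genes named as the largest changes had no overlap between the arrays of their groups. Where the lower group lay below the median probe set (4.37 in log2), as in 28 of 191 named differences past the threshold in either fit, signal is not set apart from background and the fold is not exact. Cd4 and Thy1, the gene of CD90, chose the cells and are not read as findings. Without them the T cell identity list kept its calls, and gained those with the block for persistent against no antigen with PBS (adjusted p = 0.029) and transient against no antigen with anti-CD40 (0.029).

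Antigen regime and replicate number both separated the arrays. On the first principal component (46.7% of the variance) the 6 replicate 2 arrays scored between 9.1 and 75.1, against −54.5 to 9.7 for the other 10. Replicate 2 arrays also had the lower mean intensities, 83.5 to 101 against 106 to 121. The Y-linked gene Eif2s3y had log2 intensities of 8.86 to 9.93 in the 6 replicate 1 arrays and 2.61 to 3.09 in the other 10, while Xist, which is transcribed from the inactive X chromosome, was at 5.10 to 7.16 and 9.92 to 11.31. By these genes replicate 1 held male cells and replicates 2 and 3 female cells, hence of other animals. Counts are therefore also given with the replicate number as a block in the same limma fit. Gene lists were tested with camera at a preset correlation, where 109 of 324 tests were called, and none of them with an estimated correlation (0 of 324), so a list said to have risen or fallen did so in the former test. Where 1 replicate number went the other way, the list's medians within the numbers are given.

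**Figure D1:**
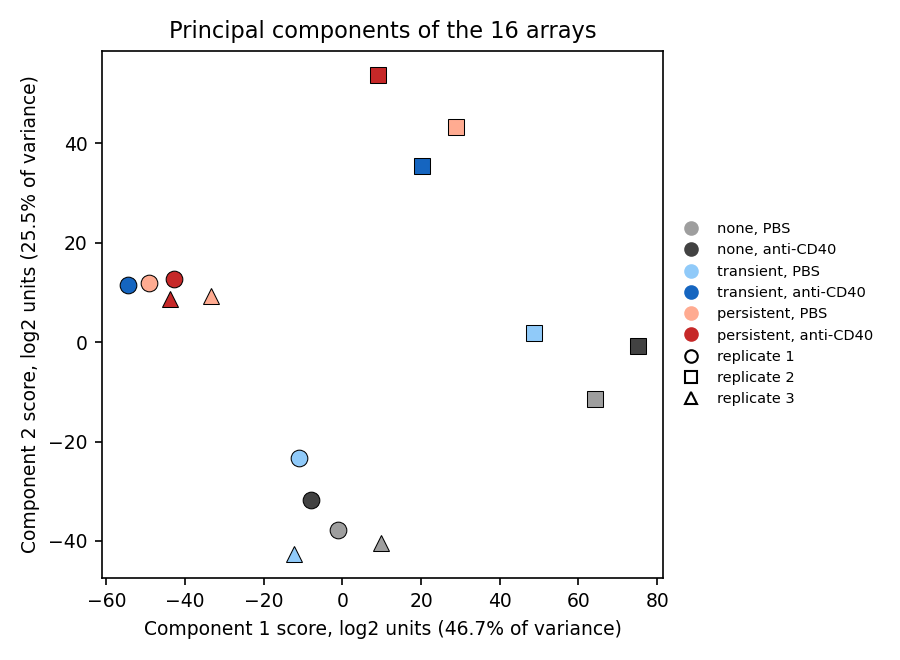
Scores of the 16 arrays on the first and second principal components (log2 units, with the percentage of variance on each axis), coloured by group and shaped by replicate number. Replicate 2 arrays lie at 9.1 or above on the first component, and within each replicate number the persistent-antigen arrays lie above the no-antigen arrays on the second.

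Transient antigen was set against no antigen, both with PBS, to ask what a passing exposure left in the T cells at 60 h. The largest increase was in Cxcr3, a chemokine receptor of Th1 cells, at 4.38 ± 0.47 (adjusted p = 0.0021). Its log2 intensity was 10.42 ± 0.41 (SD, n = 3) against 6.04 ± 0.94 (SD, n = 3). The integrin chain gene Itgb1 rose by 3.37 ± 0.49 (adjusted p = 0.015) and Cpm by 2.60 ± 0.24 (adjusted p = 7e-04). The annexin gene Anxa2 rose by 2.59 ± 0.39 (adjusted p = 0.019). Smaller increases were those of Dnajc15 (2.28 ± 0.26), Atxn1 (2.10 ± 0.25) and Rgs1 (1.27 ± 0.22). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, fell (−1.61 ± 0.23). So did Lad1 (−2.02 ± 0.33), Rnf130 (−1.52 ± 0.27), Rab6b (−1.50 ± 0.26) and Cd72 (−1.50 ± 0.21). In all 23 genes passed, 17 higher and 6 lower. After cyclic loess scaling the count was 44, 27 higher and 17 lower. Of the Th1 effector list 1 of 21 measured members rose and 0 fell (3 and 0 adjusted over the list alone). As a whole this list rose (median 0.20, camera adjusted p = 0.031, adjusted p = 0.52 with an estimated correlation). The T cell activation list fell (median −0.20, camera adjusted p = 0.031, adjusted p = 0.52 with an estimated correlation, −0.31, 0.01 and −0.19 within replicates 1 to 3), a call lost with the block (adjusted p = 0.057). In that list 1 of 25 measured members rose and 1 fell (2 and 4 adjusted over the list alone).

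Several other lists shifted after transient antigen. Mitosis genes rose (median 0.94, camera adjusted p = 7.1e-11, adjusted p = 0.52 with an estimated correlation). They had 12 higher and 0 lower members with the replicate block, led by Ccnb2 (1.78 ± 0.35), Birc5 (1.60 ± 0.29) and Cenpf (1.38 ± 0.33) (adjusted p up to 0.027). Interferon-stimulated genes rose (median 0.55, camera adjusted p = 1.5e-10, adjusted p = 0.36 with an estimated correlation). These had 13 higher and 0 lower members with the replicate block, led by Rsad2 (1.83 ± 0.34), Ifit1 (1.36 ± 0.32) and Ifi27l2a (1.32 ± 0.27) (adjusted p up to 0.022). Cholesterol synthesis genes rose (median 0.38, camera adjusted p = 0.00049, adjusted p = 0.52 with an estimated correlation). Oxidative phosphorylation rose (median 0.34, camera adjusted p = 0.00049, adjusted p = 0.52 with an estimated correlation). Glycolysis genes rose slightly (median 0.19, camera adjusted p = 0.049, adjusted p = 0.57 with an estimated correlation). Ribosome biogenesis genes fell (median −0.13, camera adjusted p = 0.00037, adjusted p = 0.52 with an estimated correlation). Dissociation and immediate early genes fell (median −0.22, camera adjusted p = 0.0069, adjusted p = 0.19 with an estimated correlation). Naive and recirculating genes fell (median −0.12, camera adjusted p = 0.036, adjusted p = 0.52 with an estimated correlation), a call the block removed (adjusted p = 0.073). With the replicate block 525 genes, 367 higher and 158 lower, passed. Among 27 measured T cell genes chosen in advance 12 then passed in place of 1. They included Ctla4, which encodes an inhibitory receptor, by 1.95 ± 0.21 (adjusted p = 2.1e-05), and the Th1 factor gene Tbx21 by 1.62 ± 0.27 (adjusted p = 0.0018). The follicular helper factor gene Bcl6 differed by −1.32 ± 0.20 (adjusted p = 0.00073) and the IL-7 receptor gene Il7r by −1.57 ± 0.26 (adjusted p = 0.0017). The other 15 passed in neither fit, with differences from −0.68 to 1.25 (smallest adjusted p = 1, and 0.073 with the block). The count without a block was 7 without none PBS 1, and the blocked one moved to 312 (transient PBS 1), 211 (transient PBS 2).

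Persistent antigen with PBS was set against no antigen with PBS to ask what continued exposure changed. A calcium-binding protein gene, S100a6, rose by 5.45 ± 0.70 (adjusted p = 0.00075). Anxa2 rose by 4.80 ± 0.39 (adjusted p = 6.1e-05) and Cxcr3 by 4.72 ± 0.47 (adjusted p = 0.00021). The cytotoxic protease gene Gzmb rose by 4.62 ± 0.66 (adjusted p = 0.0013). Its log2 intensity went from 4.63 ± 0.90 (SD, n = 3) to 9.25 ± 1.06 (SD, n = 3). Il21, a cytokine gene of follicular helper cells, rose by 4.60 ± 0.60 (adjusted p = 0.00075) and Plac8 by 4.60 ± 0.44 (adjusted p = 0.00019). The largest decreases were those of Igfbp4 (−3.73 ± 0.68), St8sia6 (−3.54 ± 0.28), Nr4a3 (−3.44 ± 0.44), Il7r (−3.14 ± 0.37), Rgcc (−3.09 ± 0.53) and Tdrp (−3.08 ± 0.33), all with an adjusted p of 0.0065 or less. In all 649 genes passed, 401 higher and 248 lower. The mitosis list rose (median 2.73, camera adjusted p = 2.3e-35, adjusted p = 0.1 with an estimated correlation). Of it 25 of 29 measured members rose and 0 fell (26 and 0 adjusted over the list alone), led by Birc5 (3.75 ± 0.52), Ccnb2 (3.47 ± 0.48), Bub1 (3.25 ± 0.67) and Cdk1 (3.22 ± 0.52). DNA replication genes rose as well (median 2.06, camera adjusted p = 2e-34, adjusted p = 0.13 with an estimated correlation). Of these 19 of 33 measured members rose and 0 fell (31 and 0 adjusted over the list alone), among them Cdc6 (3.40 ± 0.64), E2f2 (2.81 ± 0.41), Tk1 (2.51 ± 0.38) and Pola1 (2.38 ± 0.44).

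T cell programmes moved in both directions under persistent antigen. Naive and recirculating genes fell (median −1.0, camera adjusted p = 7.8e-13, adjusted p = 0.084 with an estimated correlation). Of them 1 of 24 measured members rose and 11 fell (2 and 15 adjusted over the list alone). The survival gene Bcl2 fell (−2.72 ± 0.30), as did the repressor gene Bach2 (−2.34 ± 0.22) and the lymph node homing receptor gene Ccr7 (−1.53 ± 0.25). The follicular helper list rose (median 0.95, camera adjusted p = 0.00024, adjusted p = 0.22 with an estimated correlation). In it 5 of 16 measured members rose and 0 fell (8 and 1 adjusted over the list alone), with Maf (4.29 ± 0.52), Tox2 (3.08 ± 0.45) and Cxcr5 (1.50 ± 0.22) beside Il21. The Th1 effector list rose (median 0.10, camera adjusted p = 0.011, adjusted p = 0.22 with an estimated correlation). Of its genes 6 of 21 measured members rose and 1 fell (7 and 1 adjusted over the list alone), Tbx21 at 3.29 ± 0.66 and Stat4 at 1.80 ± 0.40 among the former. The activation list had no call (camera adjusted p = 0.07). Its members Egr3 (−2.90 ± 0.44), Cd69 (−2.07 ± 0.38) and Nr4a1 (−1.64 ± 0.29) fell. Inhibitory receptor and anergy genes had none either (camera adjusted p = 0.44). There Havcr2, the gene of TIM-3, rose by 1.69 ± 0.36 (adjusted p = 0.016). Oxidative phosphorylation genes rose (median 0.74, camera adjusted p = 1.1e-10, adjusted p = 0.13 with an estimated correlation), with the cytochrome c gene Cycs at 1.11 ± 0.27. Cholesterol synthesis rose (median 0.77, camera adjusted p = 4.5e-08, adjusted p = 0.22 with an estimated correlation). So did glycolysis (median 0.77, camera adjusted p = 0.00028, adjusted p = 0.24 with an estimated correlation). In the last list Tpi1 (2.47 ± 0.45) and Pfkp (1.39 ± 0.23) rose. Its member Pdk1, whose product restrains pyruvate use in mitochondria, fell (−0.94 ± 0.22).

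Smaller list shifts accompanied persistent antigen. Interferon-stimulated genes rose (median 0.37, camera adjusted p = 0.00024, adjusted p = 0.28 with an estimated correlation). Endoplasmic reticulum stress and folding genes rose (median 0.25, camera adjusted p = 0.03, adjusted p = 0.24 with an estimated correlation). Cell death and survival genes fell (median −0.17, camera adjusted p = 0.03, adjusted p = 0.22 with an estimated correlation, 0.05, −0.27 and −0.21 within replicates 1 to 3), without a call once blocked (adjusted p = 0.12 with the block). Members past the threshold were Bcl2 (−2.72 ± 0.30), Bcl2l11 (−1.85 ± 0.34), Casp1 (1.35 ± 0.32) and Birc3 (−1.09 ± 0.25), of which Bcl2l11 encodes a pro-death protein. T cell identity genes fell (median −0.08, camera adjusted p = 0.024, adjusted p = 0.22 with an estimated correlation, −0.11, 0.07 and −0.25 within replicates 1 to 3), again not with the block (adjusted p = 0.068). Cd5 was at −1.54 ± 0.28 (adjusted p = 0.0069). Markers of NK and CD8 T cells rose (median 0.17, camera adjusted p = 0.032, adjusted p = 0.22 with an estimated correlation, −0.04, 0.30 and 0.36 within replicates 1 to 3), and lost the call with the block (adjusted p = 0.062). The cytotoxic granule genes Nkg7 (3.79 ± 0.43) and Gzmk (2.04 ± 0.32) rose. Trafficking and adhesion genes passed only with the block (camera adjusted p = 0.057 without it). They had a blocked median 0.21, camera adjusted p = 0.031, adjusted p = 0.17 with an estimated correlation. Itgb1 among them rose by 3.44 ± 0.49 (adjusted p = 0.0014). The block raised the count to 3042 genes, 1807 higher and 1235 lower. Of the genes chosen in advance 19 passed in place of 11. Among them were the effector cytokine gene Ifng by 2.77 ± 0.39 (adjusted p = 3.2e-05), Irf4 by 1.32 ± 0.22 (adjusted p = 2e-04) and Ctla4 by 1.84 ± 0.21 (adjusted p = 2.6e-06). The other 8 passed in neither fit, with differences from −0.46 to 0.63 (smallest adjusted p = 0.62, and 0.076 with the block). The count without a block was 306 without persistent PBS 1.

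**Figure D2:**
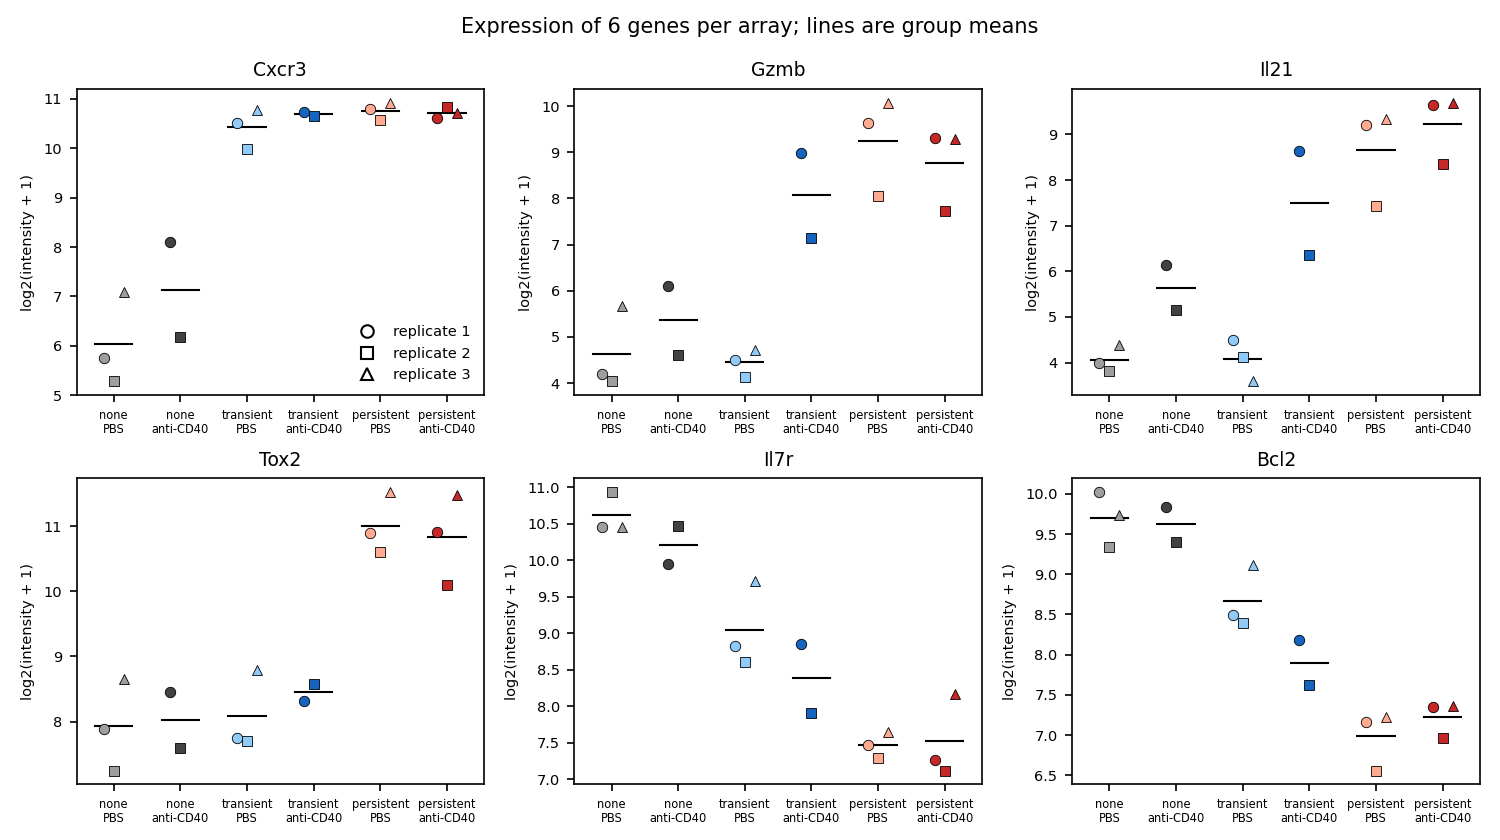
Log2(intensity + 1) of 6 genes in each array by group, with shapes for replicate numbers and horizontal lines for group means. Cxcr3 lies higher in every array with antigen than in any without, Gzmb and Il21 are near the no-antigen level after transient antigen with PBS, and Tox2, at the probe set used, is high under persistent antigen alone.

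Persistent was set against transient antigen, both with PBS, to ask what the duration of antigen altered. Gzmb rose by 4.80 ± 0.66 (adjusted p = 0.0042) and Il21 by 4.59 ± 0.60 (adjusted p = 0.0031). Their log2 intensities after transient antigen, 4.45 ± 0.29 and 4.07 ± 0.46 (SD, n = 3), lay near the median probe set, so the sizes and their rank are not exact. Neither gene had passed for transient against no antigen (−0.18 ± 0.66 and 0.01 ± 0.60). Emp1 rose by 3.83 ± 0.40 (adjusted p = 0.00058). Plek, which encodes pleckstrin, rose by 3.66 ± 0.45 (adjusted p = 0.0023) and Lgals3, the gene of galectin-3, by 3.31 ± 0.31 (adjusted p = 0.00044). The largest decreases were those of Tdrp (−3.03 ± 0.33), St8sia6 (−2.82 ± 0.28), Lypd6b (−2.55 ± 0.34), Cd86 (−2.36 ± 0.30), Cd96 (−2.19 ± 0.31) and Capn3 (−2.10 ± 0.30), each with an adjusted p of 0.0051 or less. The count was 169, 110 higher and 59 lower. DNA replication genes were higher under persistent antigen (median 1.93, camera adjusted p = 2e-40, adjusted p = 0.081 with an estimated correlation). Of them 13 of 33 measured members rose and 0 fell (31 and 0 adjusted over the list alone), among them Cdc6 (2.94 ± 0.64), Cdt1 (2.31 ± 0.24), Gins1 (2.18 ± 0.46) and Rfc4 (2.17 ± 0.47). The mitosis list was higher too (median 1.76, camera adjusted p = 8.6e-28, adjusted p = 0.1 with an estimated correlation). Of its genes 6 of 29 measured members rose and 0 fell (26 and 0 adjusted over the list alone), including Ccna2 (2.17 ± 0.42), Ttk (2.12 ± 0.44), Kif11 (1.94 ± 0.42) and Racgap1 (1.91 ± 0.37). Follicular helper genes were higher (median 0.66, camera adjusted p = 1.2e-06, adjusted p = 0.13 with an estimated correlation). Here 3 of 16 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with Tox2 (2.92 ± 0.45) and Cxcr5 (1.50 ± 0.22). Naive and recirculating genes were lower (median −0.99, camera adjusted p = 4.5e-14, adjusted p = 0.051 with an estimated correlation). In this list 0 of 24 measured members rose and 4 fell (0 and 13 adjusted over the list alone), the latter Dapl1 (−1.93 ± 0.30), Bach2 (−1.85 ± 0.22), Bcl2 (−1.68 ± 0.30) and Ccr7 (−1.41 ± 0.25).

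Further lists separated persistent from transient antigen. Oxidative phosphorylation rose (median 0.35, camera adjusted p = 1.1e-05, adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis rose (median 0.36, camera adjusted p = 0.00078, adjusted p = 0.48 with an estimated correlation). Glycolysis rose (median 0.59, camera adjusted p = 0.0046, adjusted p = 0.48 with an estimated correlation), although its member Pdk1 fell (−1.15 ± 0.22). Ribosome biogenesis rose (median 0.20, camera adjusted p = 0.03, adjusted p = 0.83 with an estimated correlation, 0.56, −0.01 and 0.19 within replicates 1 to 3). Endoplasmic reticulum stress and folding rose (median 0.27, camera adjusted p = 0.021, adjusted p = 0.28 with an estimated correlation). T cell identity genes fell (median −0.41, camera adjusted p = 0.00088, adjusted p = 0.1 with an estimated correlation). NK and CD8 T cell markers rose (median 0.25, camera adjusted p = 0.00027, adjusted p = 0.051 with an estimated correlation), with Nkg7 (2.47 ± 0.43) and Gzmk (2.34 ± 0.32). Cell death and survival genes fell (median −0.11, camera adjusted p = 0.013, adjusted p = 0.22 with an estimated correlation), a call that ended with the block (adjusted p = 0.076). In that list Bcl2l11 differed by −1.65 ± 0.34 (adjusted p = 0.037). With the block the count was 2079 genes, 1089 higher and 990 lower. Of the genes chosen in advance 14 then passed in place of 5. Il7r differed by −1.58 ± 0.26 (adjusted p = 0.00042) and Tbx21 by 1.67 ± 0.27 (adjusted p = 0.00036). Bcl6 differed by 0.89 ± 0.20 (adjusted p = 0.0057) and the IL-2 gene Il2 by −1.03 ± 0.21 (adjusted p = 0.0022). The other 13 passed in neither fit, with differences from −0.46 to 0.49 (smallest adjusted p = 0.49, and 0.12 with the block). The count without a block was 37 without persistent PBS 1, and the blocked one moved to 1334 (transient PBS 2), 1264 (persistent PBS 3). With array weights 3934 passed, 1624 higher and 2310 lower.

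**Figure D3:**
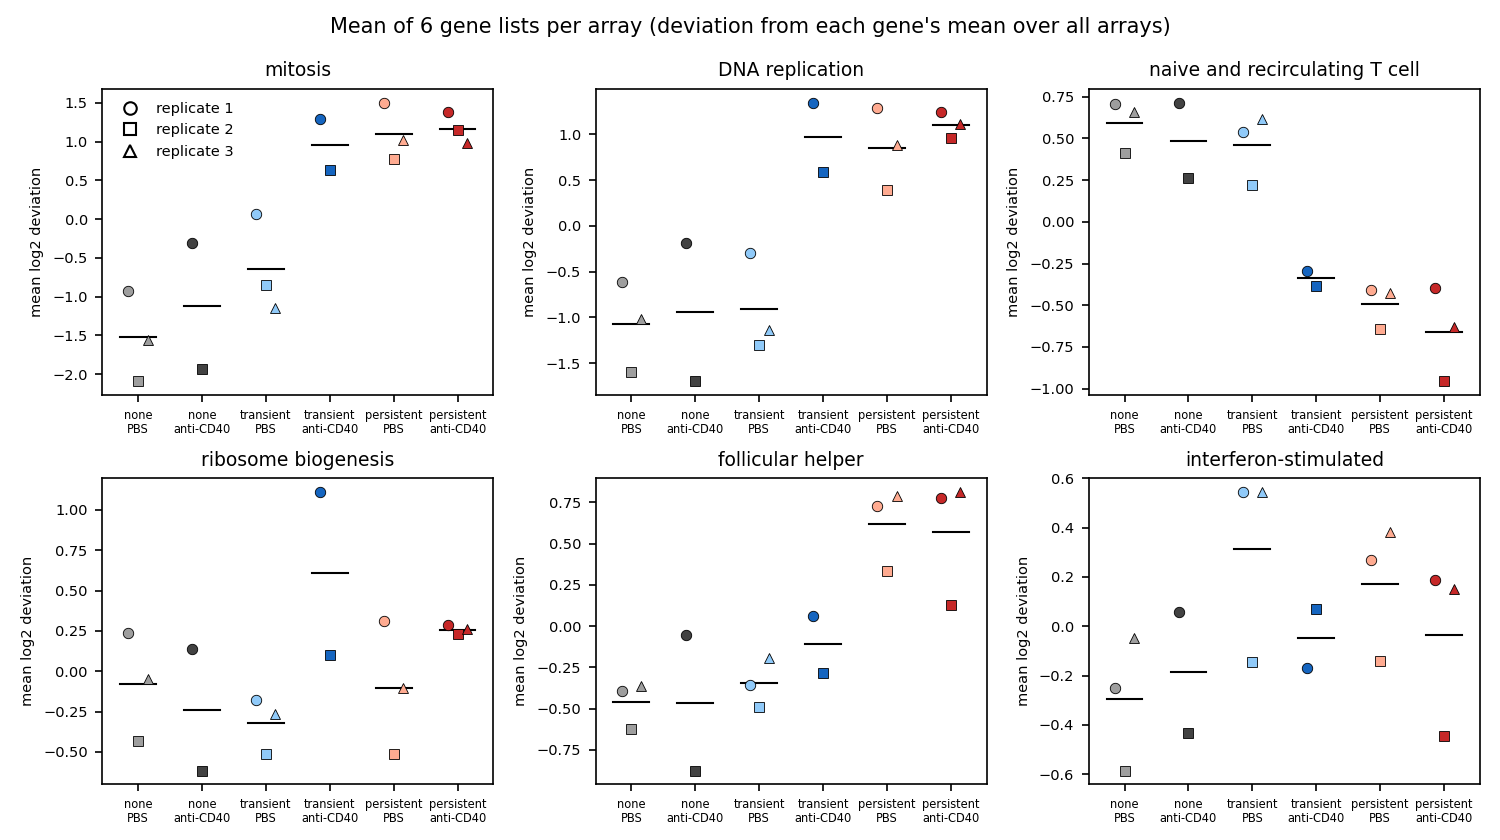
Mean deviation of the measured members of 6 gene lists from each gene's mean over all 16 arrays (log2), per array and group, with lines for group means. Mitosis and DNA replication lie above 0 in every persistent-antigen array and in both arrays with transient antigen and anti-CD40, mitosis also in 1 with transient antigen and PBS, while the follicular helper list is above 0 in all 6 persistent-antigen arrays and at 0.06 or below in the other 10.

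Anti-CD40 was compared with PBS in recipients without antigen to ask whether activated dendritic cells alone altered the T cells. No gene passed. Limma had 317 at an unadjusted p under 0.05. The smallest p-values belonged to Sphk1 (0.57 ± 0.13), Hspa1b (1.05 ± 0.24), Gucy1b1 (−0.88 ± 0.22), Acvr2b (0.63 ± 0.17) and Adamts20 (−1.24 ± 0.34), all with an adjusted p = 1. Mitosis genes rose (median 0.44, camera adjusted p = 0.0047, adjusted p = 0.93 with an estimated correlation). Dendritic cell and macrophage markers rose (median 0.17, camera adjusted p = 0.0048, adjusted p = 0.67 with an estimated correlation). Plasma cell markers rose (median 0.22, camera adjusted p = 0.022, adjusted p = 0.68 with an estimated correlation). With the replicate block 1 gene passed, named after its values were seen. It was Ccl5, a chemokine gene of effector cells, at 1.50 ± 0.22 (adjusted p = 0.032). Further lists were called only with the block. Of these, interferon-stimulated genes rose (median 0.18, camera adjusted p = 0.0029, adjusted p = 0.78 with an estimated correlation). Th1 effector genes rose (median 0.14, camera adjusted p = 0.041, adjusted p = 0.6 with an estimated correlation). B cell markers rose (median 0.21, camera adjusted p = 0.027, adjusted p = 0.51 with an estimated correlation). NK and CD8 T cell markers rose (median 0.26, camera adjusted p = 0.041, adjusted p = 0.6 with an estimated correlation). T cell activation genes fell (median −0.22, camera adjusted p = 0.027, adjusted p = 0.78 with an estimated correlation). Ribosome biogenesis genes fell (median −0.17, camera adjusted p = 0.014, adjusted p = 0.8 with an estimated correlation). Among the genes chosen in advance 27 passed in neither fit, with differences from −0.61 to 1.58 (smallest adjusted p = 1, and 0.78 with the block). The blocked count moved to 2 (none PBS 1), 3 (none PBS 3), 51 (none anti-CD40 1), 0 (transient PBS 1, persistent PBS 1, persistent PBS 3, persistent anti-CD40 2). Without none anti-CD40 1 the count without a block was 7 and the mitosis list fell (camera adjusted p = 0.041, and 8.5e-28 to 0.97 over all alternatives).

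Anti-CD40 was compared with PBS under transient antigen to ask what activated dendritic cells add to a passing exposure. Gzmb rose by 3.61 ± 0.73 (adjusted p = 0.041), Il21 by 3.42 ± 0.67 (adjusted p = 0.038) and Emp1 by 3.52 ± 0.45 (adjusted p = 0.0096). Genes of DNA replication and recombination rose with them, Dscc1 (3.04 ± 0.47), Dna2 (2.82 ± 0.57) and Trip13 (2.71 ± 0.57). The largest decreases were those of Ephx1 (−2.34 ± 0.33), St8sia6 (−2.30 ± 0.32), Tdrp (−2.09 ± 0.37), Cd86 (−1.97 ± 0.34), Adh1 (−1.77 ± 0.36) and Zbtb20 (−1.74 ± 0.30), with adjusted p-values up to 0.04. In all 116 genes passed, 95 higher and 21 lower. DNA replication genes rose (median 1.88, camera adjusted p = 4e-38, adjusted p = 0.1 with an estimated correlation). Of these 8 of 33 measured members rose and 0 fell (28 and 0 adjusted over the list alone), among them Pole (2.34 ± 0.31), Cdt1 (2.24 ± 0.27), Rfc3 (2.21 ± 0.30) and Gins2 (2.16 ± 0.36). Mitosis genes rose (median 1.62, camera adjusted p = 1.4e-20, adjusted p = 0.14 with an estimated correlation). They had 25 higher and 0 lower members with the replicate block, led by Bub1 (2.58 ± 0.35), Cdk1 (2.10 ± 0.36) and Kif20a (2.08 ± 0.35) (adjusted p up to 0.00069). Genes of naive and recirculating T cells fell (median −0.78, camera adjusted p = 5.9e-12, adjusted p = 0.1 with an estimated correlation). Of this list 0 of 24 measured members rose and 2 fell (0 and 8 adjusted over the list alone), namely Foxp1 (−1.68 ± 0.33) and Bach2 (−1.64 ± 0.25). Glycolysis genes rose (median 0.70, camera adjusted p = 2.2e-05, adjusted p = 0.28 with an estimated correlation). Among them 2 of 16 measured members rose and 0 fell (6 and 1 adjusted over the list alone). These were the hexokinase gene Hk2 at 2.48 ± 0.46 (adjusted p = 0.032) and the lactate transporter gene Slc16a1 at 1.80 ± 0.37 (adjusted p = 0.044).

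Biosynthetic lists rose in the same comparison. Ribosome biogenesis rose (median 0.80, camera adjusted p = 8.7e-16, adjusted p = 0.14 with an estimated correlation). It had 20 higher and 0 lower members with the replicate block, such as Nolc1 (1.91 ± 0.26, adjusted p = 1e-04) and Nop58 (1.90 ± 0.23, adjusted p = 4.6e-05). Cholesterol synthesis rose (median 0.48, camera adjusted p = 0.00013, adjusted p = 0.35 with an estimated correlation). With the block Idi1 rose by 2.02 ± 0.24 (adjusted p = 3.6e-05) and Sqle by 1.72 ± 0.22 (adjusted p = 5.5e-05). Endoplasmic reticulum stress and folding rose (median 0.49, camera adjusted p = 0.00017, adjusted p = 0.11 with an estimated correlation), as did oxidative phosphorylation (median 0.36, camera adjusted p = 0.00011, adjusted p = 0.3 with an estimated correlation). T cell identity genes fell (median −0.44, camera adjusted p = 0.00017, adjusted p = 0.1 with an estimated correlation). Interferon-stimulated genes fell (median −0.29, camera adjusted p = 0.0015, adjusted p = 0.42 with an estimated correlation, −0.58 and 0.19 within replicates 1 and 2). Cell death and survival genes fell (median −0.08, camera adjusted p = 0.035, adjusted p = 0.28 with an estimated correlation), not so with the block (adjusted p = 0.21). The Th1 effector list passed only with the block (camera adjusted p = 0.075 without it). It had a blocked median 0.40, camera adjusted p = 0.0095, adjusted p = 0.18 with an estimated correlation. There Tbx21 rose by 1.86 ± 0.31 (adjusted p = 0.00062) and Ifng by 2.24 ± 0.44 (adjusted p = 0.0023). Without a block Ifng differed by 1.67 ± 1.23 (adjusted p = 0.88), and by −0.39 without transient anti-CD40 1. The 3' minus 5' difference of control probe sets, a measure of RNA length, was higher with anti-CD40 by 0.64 and 0.76 for Tfrc within replicates 1 and 2, and differed by −0.12 and 0.10 for Gapdh. The block raised the count to 1912 genes, 1380 higher and 532 lower. Of the genes chosen in advance 9 passed in place of 2. The other 18 passed in neither fit, with differences from −0.67 to 0.76 (smallest adjusted p = 0.2, and 0.06 with the block). The count without a block was 0 without transient anti-CD40 1 and 0 in a fit of the compared groups alone, and the blocked one moved to 553 (transient anti-CD40 1).

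Anti-CD40 was compared with PBS under persistent antigen to ask whether activated dendritic cells add to continued exposure. No gene passed. Limma had 110 genes at an unadjusted p under 0.05. With the replicate block it called 0, had 484 at that p, and moved to 1 (persistent anti-CD40 1). The smallest p-values were those of Evc (0.45 ± 0.12), Mirt1 (−0.73 ± 0.20), Dsp (1.38 ± 0.39), Lgals7 (0.78 ± 0.22) and Crtac1 (0.43 ± 0.13), each with an adjusted p = 1. Gzmb differed by −0.48 ± 0.66 (adjusted p = 1) and Il21 by 0.57 ± 0.60 (adjusted p = 1). Small shifts of whole lists had no member past the threshold. Ribosome biogenesis rose (median 0.36, camera adjusted p = 7.4e-10, adjusted p = 0.84 with an estimated correlation, −0.04, 0.70 and 0.38 within replicates 1 to 3). DNA replication rose (median 0.25, camera adjusted p = 0.00035, adjusted p = 0.84 with an estimated correlation, −0.05, 0.54 and 0.24 within replicates 1 to 3). Glycolysis rose (median 0.25, camera adjusted p = 0.011, adjusted p = 0.84 with an estimated correlation, −0.12, 0.52 and 0.36 within replicates 1 to 3). The naive and recirculating list fell (median −0.23, camera adjusted p = 5.7e-05, adjusted p = 0.84 with an estimated correlation). Interferon-stimulated genes fell (median −0.18, camera adjusted p = 3.2e-05, adjusted p = 0.84 with an estimated correlation). Only with the block did cholesterol synthesis rise (median 0.21, camera adjusted p = 0.0014, adjusted p = 0.53 with an estimated correlation, −0.07, 0.30 and 0.37 within replicates 1 to 3). The same held for oxidative phosphorylation (median 0.10, camera adjusted p = 0.027, adjusted p = 0.8 with an estimated correlation, −0.06, 0.20 and 0.10 within replicates 1 to 3). Among the genes chosen in advance 27 passed in neither fit, with differences from −0.48 to 0.88 (smallest adjusted p = 1, and 1 with the block). Within replicates 1 to 3 the 3' minus 5' difference moved by 0.14, 1.04 and 0.00 for Tfrc and −0.01, −0.07 and −0.14 for Gapdh.

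Persistent and transient antigen were compared again with anti-CD40 given in both, to ask whether duration mattered once dendritic cells were activated. They differed in 1 gene, Dsp, which encodes the desmosomal protein desmoplakin, at 3.38 ± 0.43 (adjusted p = 0.033). Its log2 intensity was 6.53 ± 0.55 (SD, n = 3) against 3.15 ± 0.11 (SD, n = 2), the latter below the median probe set, so the fold is not exact. At an unadjusted p under 0.05 limma had 355 genes. The next smallest p-values were those of Spata5l1 (−0.95 ± 0.17), Ccdc28b (1.20 ± 0.22), Ikzf3 (1.19 ± 0.24) and Tox2 (2.38 ± 0.50) (adjusted p up to 0.94). With the block the count was 14 genes, 10 higher and 4 lower, among them Spata5l1 (−0.90 ± 0.15), Ccdc28b (1.14 ± 0.21) and Ikzf3 (1.11 ± 0.18) with adjusted p-values up to 0.039. Follicular helper genes were higher under persistent antigen (median 0.47, camera adjusted p = 1.6e-10, adjusted p = 0.2 with an estimated correlation). With the block Tox2 was at 2.05 ± 0.22 (adjusted p = 0.00015) and Pou2af1 at 1.42 ± 0.24 (adjusted p = 0.023). The naive and recirculating list was lower (median −0.20, camera adjusted p = 5.6e-06, adjusted p = 0.25 with an estimated correlation, 0.05 and −0.54 within replicates 1 and 2). With the block Satb1 was at −0.96 ± 0.17 (adjusted p = 0.035). Ribosome biogenesis genes were lower (median −0.33, camera adjusted p = 5.6e-06, adjusted p = 0.51 with an estimated correlation, −0.81 and 0.13 within replicates 1 and 2). Mitosis genes were higher (median 0.25, camera adjusted p = 0.044, adjusted p = 0.93 with an estimated correlation), as were DNA replication genes (median 0.16, camera adjusted p = 0.044, adjusted p = 0.93 with an estimated correlation, −0.08 and 0.38 within replicates 1 and 2). NK and CD8 T cell markers were higher (median 0.18, camera adjusted p = 0.027, adjusted p = 0.25 with an estimated correlation). Only with the block were plasma cell markers higher (median 0.19, camera adjusted p = 0.035, adjusted p = 0.26 with an estimated correlation). Dendritic cell and macrophage markers, too, passed only then (median 0.10, camera adjusted p = 0.018, adjusted p = 0.34 with an estimated correlation). Among the T cell genes chosen in advance 27 passed in neither fit, with differences from −1.22 to 1.73 (smallest adjusted p = 0.94, and 0.12 with the block). Dsp did not pass without any 1 of 14 of the 16 arrays, and the blocked count moved to 7 (transient anti-CD40 1, persistent anti-CD40 1), 6 (transient anti-CD40 2), 8 (persistent PBS 3), 3 (persistent anti-CD40 2), 5 (persistent anti-CD40 3). With replicate 1 and 3 arrays only, where transient antigen with anti-CD40 keeps 1 array, 39 genes passed with the block, 10 higher and 29 lower, and the mitosis and DNA replication lists had the opposite sign (camera adjusted p = 0.86 and 0.15, from 2.2e-10 to 0.97 and from 3.5e-05 to 0.97 over all alternatives).

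Antigen was also compared with no antigen among recipients that all received anti-CD40, to ask what antigen changed with activated dendritic cells. Transient antigen gave 104 genes, 77 higher and 27 lower. After cyclic loess scaling there were 232, 138 higher and 94 lower. Cxcr3 rose by 3.55 ± 0.58 (adjusted p = 0.017) and Itgb1 by 3.46 ± 0.61 (adjusted p = 0.024). The centromere gene Cenph rose by 3.27 ± 0.45 (adjusted p = 0.012) and the adhesion molecule gene Alcam by 3.14 ± 0.54 (adjusted p = 0.022). Lancl3 (3.22 ± 0.46) and Plac8 (2.90 ± 0.54) rose as well. The cholesterol exporter gene Abca1 fell (−3.43 ± 0.52), as did St8sia6 (−2.96 ± 0.35), Zbtb20 (−2.30 ± 0.33), Ephx1 (−2.30 ± 0.36), Lad1 (−2.23 ± 0.40) and Ttc28 (−2.22 ± 0.35). Persistent antigen gave 432 genes, 298 higher and 134 lower. Its largest increases were those of Alcam (3.96 ± 0.49), Il21 (3.59 ± 0.67), Cxcr3 (3.59 ± 0.53), Tbx21 (3.50 ± 0.74), Emp1 (3.42 ± 0.45) and Gzmb (3.42 ± 0.73). The largest decreases were those of Igfbp4 (−3.63 ± 0.76), St8sia6 (−3.56 ± 0.32), Tdrp (−3.35 ± 0.37), Abca1 (−3.13 ± 0.48), Trat1 (−2.98 ± 0.37) and Egr3 (−2.88 ± 0.50). These 12 genes had adjusted p-values up to 0.026.

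With anti-CD40, mitosis genes rose after transient (median 2.15, camera adjusted p = 5.6e-23, adjusted p = 0.14 with an estimated correlation) and under persistent antigen (median 2.44, camera adjusted p = 3.8e-25, adjusted p = 0.13 with an estimated correlation). DNA replication genes rose in both (median 2.02, camera adjusted p = 6.2e-30, adjusted p = 0.14 with an estimated correlation, and median 2.23, camera adjusted p = 1.3e-31, adjusted p = 0.13 with an estimated correlation). Members past the threshold included Ccna2 (2.72 ± 0.52), Ccne1 (2.24 ± 0.46) and Rfc3 (2.22 ± 0.33) after transient antigen. Under persistent antigen they included Birc5 (3.13 ± 0.58), Bub1 (3.05 ± 0.75), Ccne1 (2.58 ± 0.42) and Cdc45 (2.48 ± 0.48). Glycolysis rose in both (median 1.29, camera adjusted p = 5.9e-07, adjusted p = 0.18 with an estimated correlation, and median 1.16, camera adjusted p = 1.8e-05, adjusted p = 0.22 with an estimated correlation). Its member Tpi1 was at 2.69 ± 0.55 and 2.66 ± 0.51, Pfkp at 1.55 ± 0.28 and 1.53 ± 0.25. Oxidative phosphorylation rose in both (median 0.71, camera adjusted p = 1.3e-09, adjusted p = 0.14 with an estimated correlation, and median 0.83, camera adjusted p = 2.3e-11, adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis rose in both (median 1.08, camera adjusted p = 4.3e-08, adjusted p = 0.18 with an estimated correlation, and median 1.09, camera adjusted p = 8.8e-08, adjusted p = 0.22 with an estimated correlation). Under persistent antigen Pmvk (2.07 ± 0.40), Sqle (1.90 ± 0.46) and Stard4 (1.44 ± 0.33) passed. Ribosome biogenesis rose in both (median 0.84, camera adjusted p = 3.6e-09, adjusted p = 0.22 with an estimated correlation, and median 0.53, camera adjusted p = 0.0018, adjusted p = 0.56 with an estimated correlation). Endoplasmic reticulum genes rose in both (median 0.51, camera adjusted p = 0.00043, adjusted p = 0.14 with an estimated correlation, and median 0.30, camera adjusted p = 0.012, adjusted p = 0.22 with an estimated correlation).

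T cell lists moved in the comparisons made with anti-CD40 as follows. Naive and recirculating genes fell after transient antigen (median −0.98, camera adjusted p = 4.1e-10, adjusted p = 0.14 with an estimated correlation), with Bach2 at −1.84 ± 0.27. They fell under persistent antigen (median −1.21, camera adjusted p = 5.4e-14, adjusted p = 0.063 with an estimated correlation), with Il7r (−2.69 ± 0.41), Bcl2 (−2.39 ± 0.33) and Bach2 (−2.28 ± 0.25). Follicular helper genes rose under persistent antigen (median 1.02, camera adjusted p = 6.5e-05, adjusted p = 0.22 with an estimated correlation), with Maf (3.15 ± 0.58), Tox2 (2.80 ± 0.50) and Cxcr5 (1.48 ± 0.25). They had no call after transient antigen (median 0.37, camera adjusted p = 0.3). The Th1 effector list rose after transient (median 0.56, camera adjusted p = 0.0022, adjusted p = 0.18 with an estimated correlation) and under persistent antigen (median 0.37, camera adjusted p = 0.0018, adjusted p = 0.22 with an estimated correlation). B cell markers fell after transient antigen (median −0.43, camera adjusted p = 0.0022, adjusted p = 0.18 with an estimated correlation), with Cd72 at −1.41 ± 0.25. Under persistent antigen they were called only with the block (median −0.34, camera adjusted p = 0.036, adjusted p = 0.2 with an estimated correlation). T cell identity genes fell after transient antigen (median −0.20, camera adjusted p = 0.044, adjusted p = 0.22 with an estimated correlation, −0.50 and 0.11 within replicates 1 and 2), without a call once blocked (adjusted p = 0.059). Dendritic cell and macrophage markers did likewise (median −0.12, camera adjusted p = 0.045, adjusted p = 0.24 with an estimated correlation), again not with the block (adjusted p = 0.054). With the block the counts were 2548 genes, 1915 higher and 633 lower, for transient and 2986 genes, 1985 higher and 1001 lower, for persistent antigen. Of the genes chosen in advance 16 and 19 then passed, in place of 1 and 10. Without none anti-CD40 2 the counts without a block were 2 and 18. The transient count was 0 without transient anti-CD40 1, the blocked one moved to 1109 (none anti-CD40 2), 1067 (transient anti-CD40 1), and that of persistent antigen to 1460 (none anti-CD40 2), 1956 (persistent anti-CD40 2). Within replicates 1 and 2 the 3' minus 5' difference moved by 0.49 and 1.01 for Tfrc and −0.60 and −0.60 for Gapdh after transient antigen, and by 0.05 and 1.24 and −0.62 and −0.85 under persistent antigen.

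Transient antigen with anti-CD40 was set directly against persistent antigen with PBS, to ask how far the former differed from continued exposure. No gene passed. Limma had 633 at an unadjusted p under 0.05. The smallest p-values were those of Ikzf3 (−1.43 ± 0.24), Spata5l1 (0.97 ± 0.17), Ebi3 (1.49 ± 0.29), Tox2 (−2.55 ± 0.50) and Cxcr5 (−1.21 ± 0.25), with adjusted p-values up to 0.86. With the block 10 genes, 4 higher and 6 lower, passed. They included Ikzf3 (−1.35 ± 0.18), Spata5l1 (0.92 ± 0.15), Ebi3 (1.53 ± 0.27), Tox2 (−2.23 ± 0.22), Pou2af1 (−1.79 ± 0.24) and Dsp (−1.75 ± 0.30), the last named after its values were seen, with adjusted p-values up to 0.032. Follicular helper genes were lower after transient antigen with anti-CD40 (median −0.69, camera adjusted p = 2.4e-10, adjusted p = 0.21 with an estimated correlation). NK and CD8 T cell markers were lower (median −0.17, camera adjusted p = 0.0098, adjusted p = 0.21 with an estimated correlation). Interferon-stimulated genes were lower (median −0.21, camera adjusted p = 0.0036, adjusted p = 0.62 with an estimated correlation, −0.39 and 0.18 within replicates 1 and 2). Ribosome biogenesis genes were higher (median 0.63, camera adjusted p = 2e-15, adjusted p = 0.24 with an estimated correlation), as were glycolysis genes (median 0.29, camera adjusted p = 0.0075, adjusted p = 0.62 with an estimated correlation). Mitosis genes were lower only with the block (median −0.25, camera adjusted p = 0.00012, adjusted p = 0.59 with an estimated correlation). Cholesterol synthesis was higher only with it (median 0.25, camera adjusted p = 0.0074, adjusted p = 0.45 with an estimated correlation). So were endoplasmic reticulum genes (median 0.28, camera adjusted p = 0.013, adjusted p = 0.35 with an estimated correlation). Among the T cell genes chosen in advance 27 passed in neither fit, with differences from −1.25 to 1.41 (smallest adjusted p = 0.86, and 0.05 with the block). The count without a block was 4 without transient anti-CD40 2, and the blocked one moved to 30 (none PBS 2), 35 (none PBS 3), 19 (transient PBS 1), 6 (transient anti-CD40 1), 56 (transient anti-CD40 2), 31 (persistent anti-CD40 1), 73 (persistent anti-CD40 2). It was 118 with replicates 1 and 3 only, 96 higher and 22 lower, and 24 with an array run block, 14 and 10. Within replicates 1 and 2 the 3' minus 5' difference was higher by 0.58 and 0.81 for Tfrc and 0.01 and 0.18 for Gapdh.

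The difference made by anti-CD40 under transient antigen was set beside the difference made by persistence, both against transient antigen with PBS. Differences on both sides were large for Gzmb (3.61 ± 0.73), Il21 (3.42 ± 0.67) and Emp1 (3.52 ± 0.45) for anti-CD40 and Gzmb (4.80 ± 0.66), Il21 (4.59 ± 0.60) and Emp1 (3.83 ± 0.40) for persistence. Tox2 differed more for persistence (2.92 ± 0.45) than for anti-CD40 (0.37 ± 0.50, and 0.69 ± 0.22 with the block, adjusted p = 0.05, under the threshold before rounding). Across 18193 genes, which are not independent replicates, the log2 differences had Pearson r = 0.81 and Spearman rho = 0.68. Both sets are relative to the same 3 PBS arrays. In 100 simulations of unchanged groups against shared controls r ran from −0.71 to 0.89 with a mean of 0.40, and 5 draws reached the observed value. The covariance was 0.155 against a simulated mean of 0.019 (from −0.013 to 0.056), a difference of 0.136. With the effects taken from different replicate numbers, and so no shared array, r lay between 0.50 and 0.63 with a mean covariance of 0.134. Within replicates 1 and 2 it was 0.86 and 0.67. Of 95 genes raised by anti-CD40 and 110 raised by persistence 52 were shared, against 0.6 for independent lists. Of 21 and 59 lowered genes 13 were shared, against 0.1. With the block 824 raised and 415 lowered genes were shared, against 82.6 and 28.9. Part of the overlap may come from the shared arrays.

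**Figure D4:**
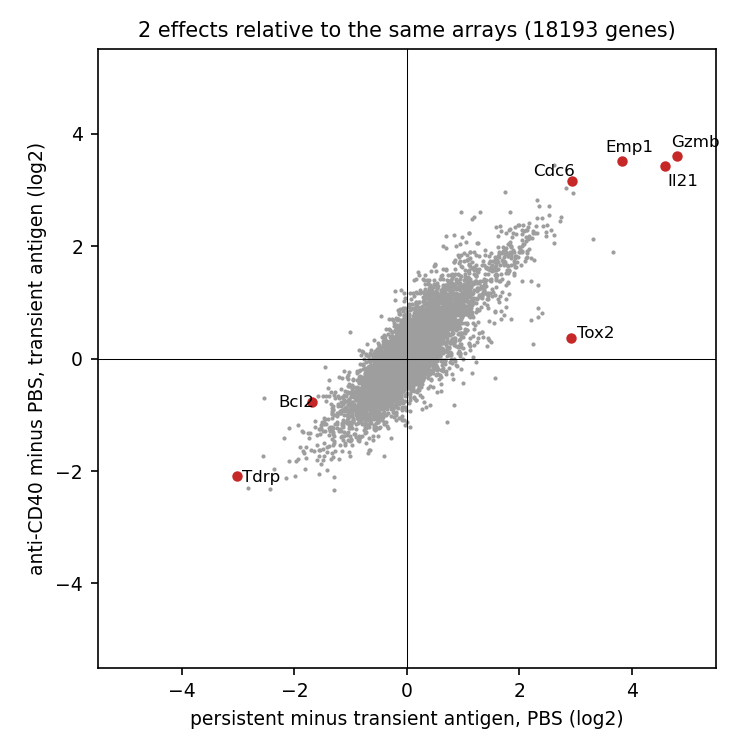
Log2 difference made by anti-CD40 under transient antigen (vertical) against that made by persistence with PBS (horizontal), 1 point per gene for 18193 genes, with named genes in red. The points run along the diagonal (r = 0.81), while Tox2 lies at 2.92 horizontally and 0.37 vertically (0.69 with the block).

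Interaction terms tested whether the effect of anti-CD40 depended on the antigen regime. No gene passed without a block. For persistent against transient antigen limma had 628 at an unadjusted p under 0.05. For transient against no antigen it had 895. The replication gene Cdt1 had the smallest p in both, at −2.08 ± 0.36 (adjusted p = 0.39) and 2.20 ± 0.38 (adjusted p = 0.44). Next came Emp1, Pole, St8sia6 and Hells in the former and Ahr, Tex15, Orc6 and St8sia6 in the latter, with adjusted p-values up to 0.39 and 0.57. With the replicate block 326 genes, 50 higher and 276 lower, passed in the former and 672 genes, 562 higher and 110 lower, in the latter. Among them were Cdt1 (−2.03 ± 0.28), Emp1 (−3.37 ± 0.44), Pole (−2.13 ± 0.36), St8sia6 (2.18 ± 0.36) and Hells (−1.73 ± 0.25) in the former and Cdt1 (2.20 ± 0.30), Ahr (2.78 ± 0.46), Tex15 (1.84 ± 0.30), Orc6 (2.23 ± 0.29) and St8sia6 (−2.23 ± 0.37) in the latter, with adjusted p-values up to 0.0079 and 0.0037. Gzmb then differed by −4.41 ± 0.44 (adjusted p = 5.3e-05) and 2.88 ± 0.46 (adjusted p = 0.0033). In the former Il21 differed by −2.98 ± 0.52 (adjusted p = 0.0087) and Tbx21 by −1.71 ± 0.42 (adjusted p = 0.041). DNA replication genes responded less to anti-CD40 under persistent than under transient antigen (median −1.66, camera adjusted p = 3.9e-36, adjusted p = 0.16 with an estimated correlation). They responded more under transient than without antigen (median 1.87, camera adjusted p = 2.2e-30, adjusted p = 0.17 with an estimated correlation). Mitosis genes differed in the same directions (median −1.60, camera adjusted p = 1.3e-21, adjusted p = 0.16 with an estimated correlation, and median 1.24, camera adjusted p = 1.2e-10, adjusted p = 0.36 with an estimated correlation). Those of naive and recirculating T cells differed in the opposite ones (median 0.76, camera adjusted p = 1.2e-07, adjusted p = 0.16 with an estimated correlation, and median −0.77, camera adjusted p = 8.1e-08, adjusted p = 0.17 with an estimated correlation). Ribosome biogenesis genes were lower in the former (median −0.52, camera adjusted p = 1.2e-07, adjusted p = 0.37 with an estimated correlation, −1.32 and 0.12 within replicates 1 and 2) and higher in the latter (median 1.06, camera adjusted p = 3e-16, adjusted p = 0.17 with an estimated correlation). Cell death and survival genes were called in the former (median 0.18, camera adjusted p = 0.0086, adjusted p = 0.19 with an estimated correlation), though not with the block (adjusted p = 0.08). Dendritic cell and macrophage markers were called in the latter (median −0.18, camera adjusted p = 0.03, adjusted p = 0.36 with an estimated correlation), though not with the block (adjusted p = 0.051). B cell markers were called there only with it (median −0.28, camera adjusted p = 0.023, adjusted p = 0.21 with an estimated correlation). The blocked counts moved to 217 (transient PBS 1), 171 (transient PBS 2), 148 (transient PBS 3), 31 (transient anti-CD40 1), 137 (persistent PBS 1), 37 (persistent PBS 3), 48 (persistent anti-CD40 1), 214 (persistent anti-CD40 3) in the former and 107 (none anti-CD40 2), 399 (transient PBS 1), 414 (transient PBS 3), 99 (transient anti-CD40 1) in the latter.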

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

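The tests in this part that weigh technical explanations were chosen only after the result was seen. Attention was drawn by the 2 interaction terms in the fit with the replicate block. Between persistent and transient antigen 326 genes passed there, against 0 without a block (limma). Without transient anti-CD40 1 it was 31, and without persistent PBS 3 37. The lists below were called by camera with the block and not with an estimated correlation. The effect of anti-CD40 was smaller under persistent antigen for DNA replication (median −1.63) and mitosis (−1.42). It was smaller as well for glycolysis (−0.54), oxidative phosphorylation (−0.37), cholesterol synthesis (−0.52) and ribosome biogenesis (−0.53). Endoplasmic reticulum stress and folding (−0.36) and NK and CD8 T cell markers (−0.29) had the same sign. Naive and recirculating genes (0.69) and T cell identity genes (0.39) had the opposite one.

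Between transient and no antigen 672 genes passed with the block, against 0 without it (limma). Without transient anti-CD40 1 it was 99. The effect of anti-CD40 was greater under transient antigen for DNA replication (median 1.87), mitosis (1.24), ribosome biogenesis (1.06) and glycolysis (0.84). It was greater too for cholesterol synthesis (0.60), oxidative phosphorylation (0.40) and endoplasmic reticulum stress and folding (0.44). Naive and recirculating genes (−0.77), T cell identity genes (−0.41) and interferon-stimulated genes (−0.41) had the opposite sign. In replicates 1 and 2, the numbers that hold all 4 groups, the DNA replication median was −1.69 and −1.27 between persistent and transient antigen, but that of ribosome biogenesis −1.32 and 0.12. Between transient and no antigen it was 1.20 and 2.08, but that of interferon-stimulated genes −0.87 and 0.09.

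Anti-CD40 raised proliferation genes under transient more than without or under persistent antigen, and no biological explanation was tested. B cells or dendritic cells in the sorted fraction would bring their own genes. Under transient antigen the 41 measured markers (26 above the median probe set with PBS) moved by −0.08 (median, SD 0.24). DNA replication genes moved by 1.93. With the block 1 marker passed as raised (Cd22), 0 as lowered. This covers that regime alone, as without antigen both marker lists rose (B cell only blocked). For the DNA replication list a single deviating replicate is argued against by within-number medians of 1.60 and 1.90. Saturation of the array under persistent antigen is argued against by Pcna, the brightest DNA replication gene, which lay 1.54 (log2) below the top of the scale with PBS and 1.33 with anti-CD40. Lower RNA quality with anti-CD40 cannot be told apart, since within replicates 1 and 2 the 3' minus 5' difference moved by 0.64 and 0.76 (mean 0.70, SD 0.08) for Tfrc and 0.20 and 0.16 for Pcx, but −0.12 and 0.10 for Gapdh and 0.06 and −0.05 for Actb.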

How the results depend on the processing

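The settings with replicates 1 and 3 only, those of the blocked counts and T cell identity and 3 of the similarity were chosen only after the results were seen. Comparisons are lettered A (transient against none with PBS), B (persistent against none with PBS), C (persistent against transient with PBS), D (anti-CD40 without antigen), E (anti-CD40 under transient antigen), F (anti-CD40 under persistent antigen), G (persistent against transient with anti-CD40), H (transient against none with anti-CD40), I (persistent against none with anti-CD40), J (transient with anti-CD40 against persistent with PBS), K (the persistence interaction), L (the transient interaction). Counts of genes called by limma without a block were 23 in A, 649 in B, 169 in C, 0 in D, 116 in E, 0 in F, 1 in G, 104 in H, 432 in I, 0 in J, 0 in K, 0 in L. The counts below lie over 1.5 times from them, those unnamed do not, and the cause was not tested unless stated. With the replicate block they were 525 in A, 3042 in B, 2079 in C, 1 in D, 1912 in E, 14 in G, 2548 in H, 2986 in I, 10 in J, 326 in K, 672 in L. With an array run block they were 401 in A, 2833 in B, 2405 in C, 2 in D, 2201 in E, 16 in G, 2223 in H, 2521 in I, 24 in J, 479 in K, 935 in L. The replicate block added or ended the list calls given in the report and no others. Of 221 named gene values 54 passed only with it and 0 only without it. In a fit of the compared groups alone, with fewer arrays for the spread, they were 0 in A, 373 in B, 12 in C, 0 in E, 0 in G, 0 in H, 1 in I. Without the intensity trend they were 209 in E, 0 in G, 214 in H, 1 in J. Without dim genes, which arrays measure nearest to background, they were 185 in E, 0 in G, 199 in H, with fewer genes tested. With the mean of probe sets they were 197 in E, 2 in G, 187 in H. After cyclic loess they were 44 in A, 359 in C, 322 in E, 0 in G, 232 in H, 670 in I. With array weights they were 458 in A, 2352 in B, 3934 in C, 57 in E, 0 in G, 0 in H, 249 in I, 5 in K. With log2(intensity + 16) they were 0 in G. With replicates 1 and 3 only they were 1355 in B, 583 in C, 831 in E, 3 in G, 6 in J, 35 in K, 2 in L, and with the block 473 in A, 3075 in B, 2152 in C, 2 in D, 2148 in E, 39 in G, 2015 in H, 1682 in I, 118 in J, 899 in K, 726 in L. At 2-fold or more 22 in A, 537 in B, 156 in C, 110 in E, 1 in G, 100 in H, 403 in I genes were left of those called.

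Without each array in turn the counts were 7 to 20 in A, 306 to 708 in B, 37 to 207 in C, 0 to 7 in D, 0 to 157 in E, 0 to 0 in F, 0 to 1 in G, 0 to 360 in H, 18 to 757 in I, 0 to 4 in J, 0 to 2 in K, 0 to 1 in L. Those over 1.5 times away follow, with the array left out named in brackets. A: 7 (none PBS 1), 10 (none PBS 2, none PBS 3), 9 (transient PBS 1), 8 (transient PBS 2), 13 (transient anti-CD40 1, transient anti-CD40 2, persistent anti-CD40 3), 12 (persistent PBS 1, persistent PBS 2), 11 (persistent PBS 3, persistent anti-CD40 1). B: 423 (none PBS 2), 306 (persistent PBS 1), 389 (persistent PBS 3). C: 60 (transient PBS 2), 42 (transient PBS 3), 37 (persistent PBS 1), 38 (persistent PBS 3). D: 7 (none anti-CD40 1). E: 48 (none PBS 1), 75 (none PBS 3), 46 (transient PBS 1), 21 (transient PBS 2), 12 (transient PBS 3), 0 (transient anti-CD40 1), 57 (persistent PBS 3), 49 (persistent anti-CD40 1), 64 (persistent anti-CD40 3). G: 0 (each array but persistent PBS 2 and persistent PBS 3). H: 68 (none PBS 3), 360 (none anti-CD40 1), 2 (none anti-CD40 2), 0 (transient anti-CD40 1), 56 (transient anti-CD40 2), 55 (persistent PBS 3), 63 (persistent anti-CD40 1), 61 (persistent anti-CD40 3). I: 757 (none anti-CD40 1), 18 (none anti-CD40 2), 153 (persistent anti-CD40 1), 191 (persistent anti-CD40 2), 157 (persistent anti-CD40 3). J: 4 (transient anti-CD40 2), 2 (persistent PBS 2). K: 2 (transient PBS 2). L: 1 (transient PBS 2). With the replicate block the counts without each array were 211 to 589 in A, 2320 to 3202 in B, 1264 to 2397 in C, 0 to 51 in D, 553 to 2153 in E, 0 to 1 in F, 3 to 18 in G, 1067 to 2870 in H, 1460 to 3264 in I, 6 to 73 in J, 31 to 449 in K, 99 to 879 in L. Those over 1.5 times from the blocked count are given in the report.
The similarity of the effects (r = 0.81) was 0.56 with each effect from a different replicate number and 0.43 without proliferation genes and those correlated with them (10730 genes kept). The last filter is set by the change compared, so that part of the fall follows from it. Without each array it was 0.59 (without transient anti-CD40 1) to 0.85.

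Of 109 list calls 109 kept direction and side of the threshold without the trend, 98 with the replicate block, 104 after cyclic loess, 94 with array weights, 39 with fry and 0 with an estimated correlation. Those of T cell identity all held without Cd4 and Thy1. Directions turned for lists in G and D. In G the mitosis list turned without transient anti-CD40 2 (camera adjusted p = 0.77) and with replicates 1 and 3 only (0.86, range 2.2e-10 to 0.97, without each array 0.0024 to 0.77). DNA replication did so in the same settings (0.14 and 0.15, range 3.5e-05 to 0.97, without each array 3.5e-05 to 0.19). Ribosome biogenesis did so without transient anti-CD40 1 (0.42, range 1.6e-25 to 0.82, without each array 8.5e-18 to 0.42). In D mitosis turned without none anti-CD40 1 (0.041, range 8.5e-28 to 0.97, without each array 8.5e-28 to 0.57). Of the gene values, Ifng in E turned to −0.39 without transient anti-CD40 1. Without each array Ifng ran from −0.39 to 3.72. Of genes not called in any setting, Gzmb turned to 0.05 in F without persistent anti-CD40 2 and to 0.34 in A without none PBS 3. Il21 turned to −0.05 in F without persistent PBS 2. In A it turned to −0.04 after cyclic loess, −0.03 without none PBS 1, −0.11 without none PBS 2, −0.20 without transient PBS 1, −0.02 without transient PBS 2 and −0.14 with replicates 1 and 3 only, blocked or not. Without each array Gzmb ran from −1.08 to 0.05 in F and −0.48 to 0.34 in A, and Il21 from −0.05 to 1.0 and −0.20 to 0.25.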

Other observations

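The tests here on replicate 2 arrays and on Egr3, Nr4a1 and Nr4a3 were chosen only after the result was seen, and the splits of the arrays were planned. Several T cell programmes had no call in any of the 12 comparisons, with or without a block. Medians of Th2 and Th17 genes ran from −0.09 to 0.14, smallest adjusted p = 0.13 (camera, without a block, as for the lists that follow). Regulatory T cell genes ran from −0.35 to 0.10 (smallest adjusted p = 0.13), inhibitory receptors and anergy genes from −0.18 to 0.20 (0.1). Trafficking and adhesion genes ran from −0.22 to 0.21 (0.057) and were called once with the block. Granulocyte markers ran from −0.22 to 0.06 (0.27) and erythrocyte markers from −0.20 to 0.14 (0.23). Those of stroma and endothelium ran from −0.12 to 0.04 (0.23).

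The 6 arrays of 2 groups of 3 split in 10 ways, so that the share of splits with as many genes cannot fall under 0.1. Transient against no antigen with PBS gave 23 (525 with the block), persistent against no antigen 649 (3042) and persistent against transient antigen 169 (2079). The highest of the other 9 splits was 0 in each, in either fit, so that 1 of 10 gave as many. Those 9 mix the groups, so that a real difference widens their spread and their 0 decides nothing. Anti-CD40 under persistent antigen gave 0 (0 with the block), which any split reaches. The highest other was 0 without and 1 with the block. Of the 10 splits 4 part all 3 replicate pairs, the real one included, and the highest other among them was 0 throughout.

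The replicate 2 arrays stood apart from replicates 1 and 3 on the first principal component. More degraded RNA in replicate 2 cannot be told apart, since the 3' minus 5' difference relative to the other arrays of a group was −1.24 (SD 0.43) for Gapdh but 0.12 (SD 0.41) for Actb, 0.23 (SD 0.41) for Tfrc and 0.32 (SD 0.15) for Pcx, the last higher in 6 of 6 groups. Sex of the donor cells is argued against by replicate 3, which shared low Eif2s3y with replicate 2 but lay nearer to replicate 1 in 4 of 4 groups with 3 arrays. Array run cannot be told apart from replicate number, since each of the 4 runs holds a single number. The 2 runs of replicate 2 differed in mean deviation by 6.9 while replicate 2 lay 66.8 from the others. The labels name no difference between replicate numbers, and no other biological one was tested.

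Egr3, Nr4a1 and Nr4a3, set together after their values were seen, were lower with persistent antigen than without, while Egr2 did not pass (−0.46 ± 0.38 (adjusted p = 0.74)) and the activation list had no call, so no programme is read from them and no biological explanation was tested. Handling during isolation as the whole cause is argued against by the dissociation and immediate early list, whose median was −0.03 (SD 0.43) for persistent against no antigen with the block. Within replicates 1 to 3 its medians were −0.14, −0.28 and −0.24, so that a small part stays open. For transient against no antigen with PBS the same list was called (median −0.22, without a block), so that this reading holds for persistent antigen alone. Lower RNA quality with antigen cannot be told apart here, as the Gapdh 3' minus 5' difference within replicate numbers was −0.49 (SD 0.59), no more than its spread. The recipients' genotype, doxycycline and, in replicate 2, array run stay open too.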
